A study of Mus musculus with 12 samples.

How the data were processed

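Thymocytes from RTOC at day 6 were measured on 12 Affymetrix mouse arrays, 4 each of OT1, HY_low and HY_high, as the titles of the samples group them. The values are intensities on a linear scale, as deposited by the authors in a single table of 12488 probe sets. How these intensities were background corrected, summarised and scaled is not given in the sources used here. The lowest value in the table is 1, and the medians of the arrays differ by a factor of 1.19 at most, so the arrays were used as deposited, without further scaling. Like medians do not show that the low ends of the arrays are comparable. The share of values at 1 ran from 3.00% on HY_high array 2 to 22.5% on HY_high array 3. Among arrays numbered 2 it was 19.0% in OT1, 5.18% in HY_low and 3.00% in HY_high, which bears on differences of dim probe sets.

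Control probe sets, 66 in number, were left out of the tests, which left 12422. Values were to be raised to the 10th percentile of the table, but that percentile is 1, the lowest value, so this step changed nothing. All values were put on a log2 scale. A probe set was tested if its mean log2 value over the 12 arrays lay above the 30th percentile of those means, an intensity of 1.76, which kept 8695. Probe sets were matched to genes with the platform's annotation, current symbols being looked up by gene ID. Of the 12422 probe sets 10833 matched 1 gene, 396 several and 1193 none. In the tested set these numbers were 7718, 295 and 682. No genome was given for these probe sets, so no positions are reported.

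The 3 comparisons were HY_high with HY_low, HY_low with OT1, and HY_high with OT1. One limma fit (version 3.58.1, R 4.3.3) held a mean for each group over all 12 arrays, with 9 residual degrees of freedom, and empirical Bayes moderation of the variances used a trend on intensity. Tests were two-sided with Benjamini-Hochberg adjustment over the tested probe sets, at a threshold of 0.05. Differences are log2 and given with their standard errors. Group levels are geometric means. The first comparison changes the peptide dose as the labels describe it. The sample titles also carry different letters, ab in HY_low and aa in HY_high, which are not explained. Dose cannot be told apart from whatever these letters mark. The other 2 comparisons change the receptor and, as far as the labels say, the peptide.

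Arrays of the groups share the numbers 1 to 4. Deviations from the group means were correlated between arrays of different groups to see whether the numbers pair them. The 12 pairs with the same number had correlations from 0.341 to 0.593, and the 36 other pairs from -0.40 to 0.163. Each of the 12 arrays correlated best with one of its own number. The first principal component held 29.3% of the variance, 94.8% of it between numbers, and the second 20.1%, with 96.6% between numbers. The numbers therefore pair the arrays, as the data show and the labels do not state. A fit with the number as a block, 6 residual degrees of freedom, was computed beside the fit without it. Where it changes a call, its value or the count of its calls is given. The highest share of equal values above 8 between any pair of arrays was 0.127%.

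RNA quality was compared with the log2 ratio of the 3' to the 5' control probe sets. For Gapdh the group means were 4.62 in OT1, 4.80 in HY_low and 4.55 in HY_high, and for actin 2.86, 2.63 and 2.63. Two-sided exact permutation tests between groups gave p from 0.514 to 1, where the smallest p that 4 against 4 arrays can give is 0.0286. Single arrays ran from 2.95 (OT1 array 4) to 6.26 (OT1 array 2) for Gapdh. Arrays numbered 2 had 5.60 to 6.26 and those numbered 4 had 2.95 to 3.27, and the tests did not pair arrays by number. The tests compare groups only and do not show that the RNA was intact.

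Gene lists, 25 in number, covered TCR activation, NK receptors and adaptors, cytotoxic effectors and chemokines, innate-like lymphocyte regulators, double-positive thymocyte and mature conventional T cell genes, T cell receptor signalling components, cytokine receptors, interferon response, cell cycle, apoptosis, immediate early and heat shock genes, glycolysis, cholesterol synthesis, ribosomal proteins, sex-linked genes, and markers of 9 other cell types. Each gene was represented by its brightest probe set with 1 symbol. Lists with at least 4 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, again with the correlation estimated from the data, and with fry. Members were counted over all genes tested and adjusted over the list alone.

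Genes were named by a rule. Among probe sets with 1 symbol, an adjusted p under 0.05 and no overlap between the groups, the rule took up to 12 rises and 12 falls per comparison. It added up to 4 members of each list with the smallest p, and up to 6 T cell receptor variable probe sets past the threshold. In a comparison with fewer than 5 calls it added the 10 smallest p. The rule was repeated with the block. A gene named outside it is said to have been chosen after its values were seen.

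The fit was tested on simulated data, 5 runs of HY_high against HY_low with 200 of 8695 probe sets changed. Without the block, 0% of the 2-fold, 28.1% of the 4-fold and 72.4% of the 8-fold changes were recovered, with 0.893% false calls. With the block these shares were 28.4%, 88.1% and 96.1%, with 5.40% false calls. A shifted list of 20 genes was found in 5 of 5 runs and an unshifted one in 0. The changed probe sets and the shifted list were drawn only from baselines above 8, and the noise was independent between genes. The recovered shares therefore do not apply to dim probe sets. The list result does not apply to genes that vary together, as in the interferon list (estimated correlation 0.18).

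Alternatives fixed in advance were quantile normalization, scaling to one median, log2 of the value plus 1, a floor at the 25th percentile (1.38), no filter, a filter at the median, no intensity trend, a fit of only the groups compared, array weights, the replicate block, a 2-fold minimum, the mean of a gene's probe sets for the lists, and leaving out each array in turn. A floor at 8, leaving out the 3 arrays numbered 1, both of these with the block, and the double-positive list without Cd8b1 were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.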

Results

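Expression was measured on 12 Affymetrix mouse arrays of thymocytes taken from RTOC, a culture in which thymocytes are reaggregated with thymic stroma, at day 6. The cells carried either of 2 transgenic T cell receptors. OT1 is a class I restricted receptor for an ovalbumin peptide, and HY is a class I restricted receptor for a male peptide encoded by Smcy. The labels define 3 groups of 4 arrays, numbered 1 to 4 in each group. The first held OT1 thymocytes with no peptide named (OT1). The other 2 held HY thymocytes with Smcy peptide at 1e-07 M (HY_low) or at 1e-05 M (HY_high). The deposited intensities had a median of 3.71 and a lowest value of 1, which 15.3% of the values took. Median intensity per array lay between 3.33 and 3.97, and the number of arrays limits the precision. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between arrays.

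The comparison of HY_high with HY_low asks how thymocytes with the same receptor differed between a higher and a lower dose of the agonist peptide. The sample titles also differ, with the unexplained letters aa in HY_high and ab in HY_low, so an effect of dose cannot be separated from what they mark. Of 8695 probe sets tested with limma, 2 passed an adjusted p of 0.05, 1 higher and 1 lower in HY_high. With the replicate number as a block the count was 30, 20 higher and 10 lower, and it included both. An unadjusted p under 0.05 was found for 257 probe sets. The groups did not overlap in 2.02% of probe sets. Chance gives 2.86% where arrays are exchangeable, but same-numbered arrays are alike, and the 7 other splits that part each such pair, counted after the results were seen, gave 0.991% on average and at most 1.56%.

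Cd8b1, which encodes the beta chain of the CD8 coreceptor, was lower in HY_high than in HY_low. Whether the cells of the groups were picked by CD8 beta is not stated in the labels. Its geometric mean intensity was 4.52 in HY_high and 644 in HY_low, 143-fold lower (log2 difference -7.15 ± 0.75 SE, n = 4 per group, limma adjusted p = 0.000252). It was lower within 4 of 4 numbers, which the naming rule fixes by asking for groups without overlap. Without the filter on dim probe sets the adjusted p was 0.0555, the highest under any alternative. With intensities under 8 set to 8, a floor chosen after the data were seen, the difference was -6.31 (adjusted p = 0.00291). Cd8a, which encodes the alpha chain and was singled out after its values were seen, had a geometric mean of 157 in HY_high and 339 in HY_low. Its log2 difference of -1.11 ± 0.58 did not pass (adjusted p = 1), and it was lower within 4 of 4 numbers.

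Klrb1a, a lectin-like receptor of natural killer (NK) cells, rose from a geometric mean of 1.49 to 10.3 (log2 difference 2.79 ± 0.46 SE, n = 4 per group, limma adjusted p = 0.0487). Its rise within 4 of 4 numbers was fixed by the same rule. Both intensities lie near the bottom of the scale. With the floor at 8 the difference was 0.44 and the adjusted p 1. The call was lost under 13 of 21 alternatives. Those include leaving out any 1 of HY_low arrays 2, 3 and 4 or of the 4 HY_high arrays, which gave adjusted p from 0.0632 to 0.250. The comparison then had 1 probe set past the threshold, and 4 without HY_low array 1.

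Several genes with the next smallest p were also higher in HY_high without passing. Car2, a carbonic anhydrase, had a log2 difference of 3.49 ± 0.60 (limma adjusted p = 0.0550, or 0.00430 with the block). Cd244a, an NK cell receptor of the SLAM family, had 2.68 ± 0.49 (adjusted p = 0.0792, or 0.0126 with the block). For Fcer1g, the signalling adaptor of Fc and NK receptors, the difference was 2.62 ± 0.49 (adjusted p = 0.0825, or 0.00718 with the block). HY_low lay near the lowest value for Fcer1g (1.34). With the floor at 8 the differences of Car2, Cd244a and Fcer1g were 1.85, 1.14 and 0.37. Casp1, the caspase that processes interleukin-1, had 2.03 ± 0.40 (adjusted p = 0.133, or 0.0383 with the block). It lay below 8 on all arrays, with 1.26 in HY_low and 5.15 in HY_high, and had no value with the floor. Ahnak had 2.31 ± 0.51 (adjusted p = 0.251, or 0.000714 with the block). Over the alternatives the adjusted p ranged from 0.00291 to 0.288 for Car2, from 0.00710 to 0.337 for Cd244a, and from 0.00718 to 1 for Fcer1g. The range was 0.0325 to 0.501 for Casp1 and 0.000714 to 1 for Ahnak. Socs3, a suppressor of cytokine signalling, was lower by the same measure, at -1.86 ± 0.41 (adjusted p = 0.251, or 0.00689 with the block), and its other probe set gave -2.27. Its adjusted p ranged from 0.00689 to 0.996.

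Among the genes that passed only with the block, Bcl2l11, which encodes the pro-apoptotic protein Bim, had a log2 difference of 1.51 (block adjusted p = 0.0126). A further, dimmer probe set of Bcl2l11 gave -1.05. Id2, a regulator of innate lymphocyte development, had 2.17 (block adjusted p = 0.0104), Lat2 had 2.51 (0.0467) and Emb 1.36 (0.0155). Lat2 was dim in HY_low, with a geometric mean of 2.89 against 16.5 in HY_high. Its difference ranged from 1.04 to 2.84 over the alternatives. Lower values were found for Il6ra, the interleukin-6 receptor chain, at -2.40 (block adjusted p = 0.0281), and for Sit1, an inhibitory adaptor of the T cell receptor, at -1.53 (0.0383). Il6ra was dim in HY_high, with a geometric mean of 3.29 against 17.4 in HY_low. Its difference ranged from -2.90 to -1.21 over the alternatives. Thy1, Cd9 and Anxa2, chosen after their values were seen, had -1.24 (block adjusted p = 0.0126), 1.76 (0.0196) and 1.75 (0.0281). For these 9 genes the block value was the lowest adjusted p under any alternative, the reported value was 0.815 or higher, and no alternative without the block gave one under 0.211.

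**Figure D1:**
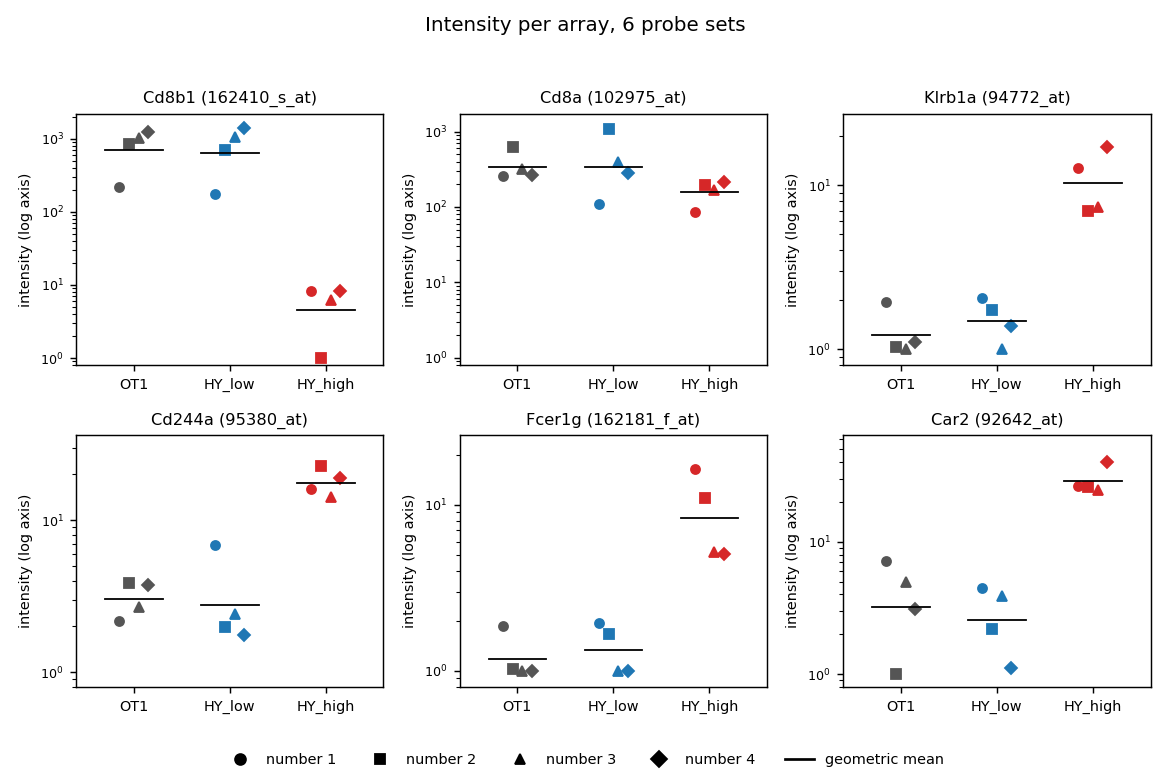
Intensity on a log axis of 6 genes on each array of OT1, HY_low and HY_high, where each marker shape stands for an array number and each line for the group's geometric mean. Cd8b1 had a geometric mean of 4.52 in HY_high against 644 in HY_low, whereas Cd8a had 157 against 339.

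Of the 25 lists of genes fixed before the data were examined, knowing that the study concerned agonist-selected thymocytes with features of innate immune cells, 23 had at least 4 measured genes and were tested with limma's camera. In HY_high against HY_low 7 passed, 6 higher and 1 lower. The list of NK receptors and adaptors was higher (15 genes, median log2 difference 1.02, adjusted p = 4.55e-10) and passed also with an estimated correlation between genes (adjusted p = 0.00330). Its within-number medians were 1.11, 1.85, 0.87 and 1.16. Many of its genes are dim, with 3 of the 15 above 8 in OT1 and 8 of them still tested with the floor at 8 (median 1.01, still past the threshold). The lowest median under any alternative was 0.58, without the filter. Of its 15 genes 1 rose over all genes tested, 5 did when adjusted over the list alone, and 3 did with the block. Klrd1, a subunit of an inhibitory NK receptor, was among the brighter members, with a geometric mean of 198 against 42.9 (log2 difference 2.21, adjusted p = 1). HY_low array 2 was at 8.75, and without it the Klrd1 difference was 1.44. The list of NK cell markers was higher without passing (4 genes, median 0.29, camera adjusted p = 0.198), with 0.16, 0.74, 0.20 and 0.21 within the numbers. All 4 genes also belong to another list, 0 lay above 8 in OT1, and 1 was still tested with the floor at 8. This list is therefore not separate from the others and can say little of NK cells. RNA of NK cells, not tested here, stays open.

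The list of double-positive thymocyte genes was lower (16 genes, median -0.42, adjusted p = 0.000673, or 0.0898 with an estimated correlation). Without Cd8b1 its adjusted p was 0.0303. Rag1 and Dntt, which act in receptor gene rearrangement, had log2 differences of -1.44 and -1.32 and did not pass. Both are dim (2.58 against 7.00 and 3.67 against 9.13), with the floor at 8 the differences were -0.07 and -0.26, and the other Dntt probe set gave -0.50. The interferon response list was higher (29 genes, median 0.41, adjusted p = 0.00216, or 0.381 with an estimated correlation), as were cytotoxic effectors and chemokines (18 genes, median 0.35, adjusted p = 0.00291, or 0.0898). The remaining calls were TCR activation (24 genes, median 0.37, adjusted p = 0.0280, or 0.381, and 0.0623 with the block), apoptosis (20 genes, median 0.14, adjusted p = 0.0280, or 0.381, with medians from -0.05 to 0.29 over the alternatives) and innate-like lymphocyte regulators (16 genes, median 0.37, adjusted p = 0.0316, or 0.144). Each of these 5 raised lists had a median below 0 within 1 number, at -0.03 for interferon, -0.15 for cytotoxic effectors, -0.07 for TCR activation, -0.02 for apoptosis and -0.14 for innate-like regulators. Their calls were lost under 3, 5, 14, 11 and 10 of 25 alternatives, in that order, against 0 for the NK list and 2 of 26 for the double-positive list. No gene of the interferon, cytotoxic, TCR activation or innate-like lists passed alone, over all genes or adjusted over the list alone, while 2 apoptosis genes did over the list alone. The number of lists past the threshold was 4 without HY_low array 2, 3 without HY_high array 3 and 4 without HY_high array 4. The other 16 lists had medians from -0.18 to 0.39 and adjusted p from 0.198 to 0.862.

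The comparison of HY_low with OT1 asks how thymocytes with the HY receptor at the lower peptide dose differed from OT1 thymocytes. Receptor and peptide changed together, so their effects cannot be separated. By limma 2 of 8695 probe sets passed, 1 higher and 1 lower in HY_low, and with the replicate number as a block 8 did, 7 higher and 1 lower. An unadjusted p under 0.05 was found for 230, and the groups did not overlap in 1.63%, where chance gives 2.86% for exchangeable arrays and the 7 other splits that part the pairs gave 0.969% on average and at most 1.12%.

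Trav9d-3, a T cell receptor alpha variable segment, rose from a geometric mean of 127 in OT1 to 2973 in HY_low (on the probe set brighter in HY cells, log2 difference 4.55 ± 0.45 SE, n = 4 per group, limma adjusted p = 0.000115). A second of its 3 probe sets had a log2 difference of 2.87 ± 0.51 (adjusted p = 0.0680, or 0.00141 with the block), and the last, near the lowest value, had -0.29 (1.83 against 2.25). A probe set that the annotation does not name, singled out after its values were seen, fell from 116 to 3.79 (log2 difference -4.93 ± 0.54, adjusted p = 0.000260). Both calls held under 22 of 22 alternatives, with the highest adjusted p at 0.00950 for Trav9d-3 and 0.0465 for the unnamed probe set. The size of the latter rests in part on dim values in HY cells, since with the floor at 8 its log2 difference was -3.86 (adjusted p = 0.0212). Trbv13-2, a beta variable segment, was read in opposite directions by its 2 probe sets. The one dimmer in OT1 had a log2 difference of 3.07 (adjusted p = 0.0678, or 0.00171 with the block), and the other, of a type that can read several family members, had -1.75 (adjusted p = 1). The brighter Trav9d-3 probe set is of that type as well. The block also gave calls for H2-K1, a class I molecule, at 3.39 on 1 probe set (block adjusted p = 0.00155), where its other probe sets gave 0.26 and 0.27. Trgv1, a gamma chain variable segment, had 1.14 (block adjusted p = 0.0115) and Slc9a3r1 1.21 (0.0323). Of these 5 block calls, none had a lower adjusted p under any other alternative, and each reported value lay at 0.0678 or above. Without the block, Trbv13-2 passed with quantile normalization (adjusted p = 0.0367), scaling to one median (0.0352) and array weights (0.00368), and the second Trav9d-3 probe set without OT1 array 3 (0.0333). The other 3 passed under no alternative without the block. OT1 lay near the lowest value for Trbv13-2 (2.34) and H2-K1 (2.52), and with the floor at 8 their differences were 1.29 and 1.74 (adjusted p = 1 for both).

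**Figure D2:**
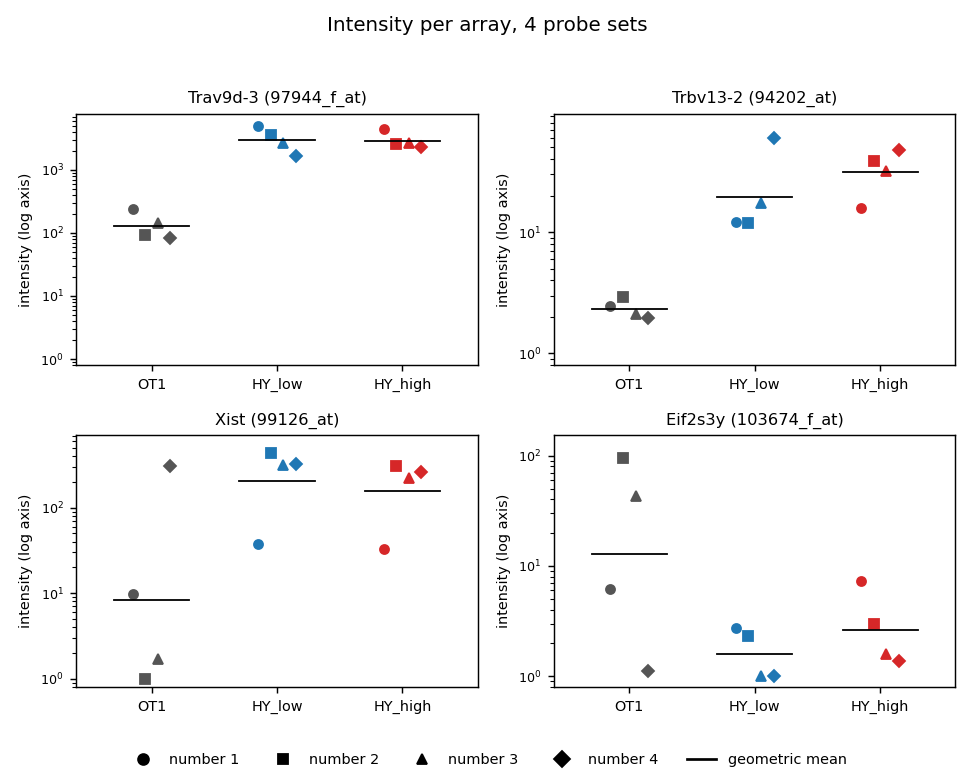
Intensity on a log axis of Trav9d-3, Trbv13-2, Xist and Eif2s3y on each array of OT1, HY_low and HY_high, where each marker shape stands for an array number and each line for the group's geometric mean. Trav9d-3 had a geometric mean of 127 in OT1 against 2973 in HY_low, and Xist ran from 1 to 304 among the OT1 arrays.

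Cd8b1, singled out after its values were seen, had a geometric mean of 644 in HY_low and 693 in OT1 (log2 difference -0.10 ± 0.75, limma adjusted p = 1). Of the lists, 2 were higher in HY_low by camera. The interferon response list had a median of 0.66 (29 genes, adjusted p = 4.27e-11, or 0.120 with an estimated correlation), with within-number medians of 0.08, 0.88, 0.92 and 1.06. Markers of macrophages and dendritic cells were higher too, without passing (20 genes, median 0.32, adjusted p = 0.184), with 0.05, 0.52, 0.49 and 0.32 within the numbers and 2 genes past the threshold over the list alone. Among them Apoe went from 1.27 to 5.61 and Lyz2 from 1.16 to 4.57 (adjusted p = 1 for both), so RNA of such cells, not tested here, stays open. The B cell markers also had a higher median without passing (9 genes, 0.44, adjusted p = 0.184), with 0.54, 0.16, 0.43 and 0.30 within the numbers, and B cells stay open in the same way. For TCR activation the median was 0.56 (24 genes, adjusted p = 2.72e-05, or 0.120). Its call was lost under 4 of 25 alternatives, with a lowest median of 0.08, against 2 of 25 and 0.48 for the interferon list. No member of either list passed over all genes, while 2 TCR activation genes and 0 interferon genes did when adjusted over the list alone. Glycolysis did not pass (16 genes, median -0.29, adjusted p = 0.126), but was lower under 3 of 25 alternatives, with the block (adjusted p = 0.0339), with array weights (0.0403) and without OT1 array 2 (0.0123). The other 21 lists, glycolysis included, had medians from -0.29 to 0.44 and adjusted p from 0.126 to 0.999. Xist, the transcript of the inactive X chromosome, had a log2 difference of 4.60 ± 1.33 and Y-linked Eif2s3y had -3.02 ± 1.02. Neither passed (adjusted p = 1 for both). On OT1 arrays 1 to 4 Xist was at 9.89, 1, 1.68 and 304 and Eif2s3y at 6.12, 95.5, 43.0 and 1.11, a spread that the groups do not explain.

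The comparison of HY_high with OT1 sets the higher dose against the same OT1 arrays, under the same limit. Of 8695 probe sets, 15 passed with limma, 12 higher and 3 lower in HY_high, and with the replicate number as a block 118 did, 98 higher and 20 lower, the 15 among them. An unadjusted p under 0.05 was found for 355, and the groups did not overlap in 2.53%, where chance gives 2.86% for exchangeable arrays and the 7 other splits that part the pairs gave 0.978% on average and at most 1.69%. The count was 6 without OT1 array 2, 9 without OT1 array 3, 7 without OT1 array 4, 7 without HY_high array 2, 6 without HY_high array 3 and 9 without HY_high array 4.

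Cd8b1 fell to 4.52 from 693 (log2 difference -7.26 ± 0.75 SE, n = 4 per group, limma adjusted p = 6.8e-05), or by 6.42 with the floor at 8, a bound for a gene so dim in HY_high (adjusted p = 0.00194). The unnamed probe set fell by 5.47 (adjusted p = 6.66e-05), or by 3.86 with the floor at 8, where it also passed. St6galnac2, a sialyltransferase, fell by 3.18 ± 0.57 (adjusted p = 0.0258). The receptor segments rose, Trav9d-3 by 4.50 and 3.20 on 2 of its 3 probe sets (adjusted p = 6.66e-05 and 0.0127) and Trbv13-2 by 3.74 on the probe set dimmer in OT1 (adjusted p = 0.00453). The last Trav9d-3 probe set, near the lowest value, had -0.52 (1.57 against 2.25) and did not pass. Calls were lost under 9 of 22 alternatives for St6galnac2 (adjusted p up to 0.838, with the floor at 8), 5 for the second Trav9d-3 probe set (up to 0.114) and 2 for Trbv13-2 (up to 0.577, with the floor at 8), and under none for the other 3. The other Trbv13-2 probe set had -1.80 (adjusted p = 0.743, or 0.0286 with the block, range 0.0212 to 1).

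The NK receptor genes Klrb1a, Fcer1g and Cd244a rose by 3.07 ± 0.46, 2.82 ± 0.49 and 2.54 ± 0.49 (limma adjusted p = 0.00580, 0.0229 and 0.0406). Crtam, a surface molecule of activated cytotoxic lymphocytes, rose by 2.91 ± 0.52 (adjusted p = 0.0258) and Capn3, a calpain protease, by 2.87 ± 0.51 (adjusted p = 0.0258). Dimmer probe sets of Capn3 had 1.41 and 1.67 and did not pass (limma adjusted p = 0.307 for the latter). Car2 rose by 3.16 ± 0.60 (adjusted p = 0.0398) and Casp1 by 2.04 ± 0.40 (adjusted p = 0.0494). Each of these 7 genes was higher within 4 of 4 numbers. The naming rule fixed this by asking for groups without overlap, so it adds no support. Their calls were lost under some of up to 22 alternatives, namely 2 for Klrb1a, 10 for Fcer1g, 11 for Cd244a, 11 for Crtam, 9 for Capn3, 10 for Car2 and 12 for Casp1. Leaving out any 1 of the 8 arrays ended the call of Cd244a and of Casp1. With the floor at 8 Klrb1a, Fcer1g and Crtam had differences of 0.44, 0.37 and 0.47 and did not pass. Car2 and Cd244a passed with that floor, but with differences of 1.85 and 1.14. Casp1 lies below 8 on all arrays and had no value with it.

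In this comparison 6 lists passed by camera. The interferon response list was higher (median 1.22, adjusted p = 2.97e-19, or 0.0152 with an estimated correlation). Of its 29 genes 0 passed over all genes, 12 rose when adjusted over the list alone, and 7 with the block, among them Usp18 (log2 difference 3.27, block adjusted p = 0.00145) and Iigp1 (2.93, block adjusted p = 0.00624). Their adjusted p without the block was 0.187 and 0.0586, and the range over the alternatives was 1.84e-05 to 0.628 and 0.00510 to 1. With the floor at 8 the differences of Usp18 and Iigp1 were 2.62 and 0.69. NK receptors and adaptors were higher (median 1.33, or 0.52 without the filter, adjusted p = 6.01e-10, or 0.00416 with an estimated correlation), with 3 of 15 genes past the threshold, 7 when adjusted over the list alone and 5 with the block. TCR activation was higher (median 0.86, adjusted p = 6.01e-10, or 0.0152), with 0 of 24 genes over all genes, 5 over the list alone and 4 with the block. These include Nr4a2, an immediate target of receptor signalling (2.29, adjusted p = 0.103, or 0.0107 with the block, range 0.0101 to 1). Nr4a2 is dim (1.63 in OT1), and with the floor at 8 its difference was 0.26. Cytotoxic effectors and chemokines were higher (median 0.81, adjusted p = 8.25e-05, or 0.0198), with 0 of 18 genes, and 1 with the block, which was the chemokine gene Xcl1 (2.55, or 1.58 with the floor at 8, adjusted p = 0.0657, or 0.00159 with the block, range 0.00159 to 0.466). Over the alternatives the lowest medians were 0.69 for interferon, 0.32 for TCR activation and 0.16 for cytotoxic effectors, with no call lost.

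Apoptosis genes were higher (median 0.43, adjusted p = 0.00133, or 0.146 with an estimated correlation), with 1 of 20 past the threshold, 2 over the list alone and 2 with the block. Double-positive thymocyte genes were lower (median -0.29, adjusted p = 0.00133, or 0.0768), with 1 of 16 past the threshold, 3 over the list alone and 3 with the block. The within-number medians were -0.57, 0.02, -0.54 and -0.18. Without Cd8b1 that list had an adjusted p of 0.0704. The other 17 lists had medians from -0.16 to 0.50 and adjusted p from 0.0552 to 0.956.

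**Figure D3:**
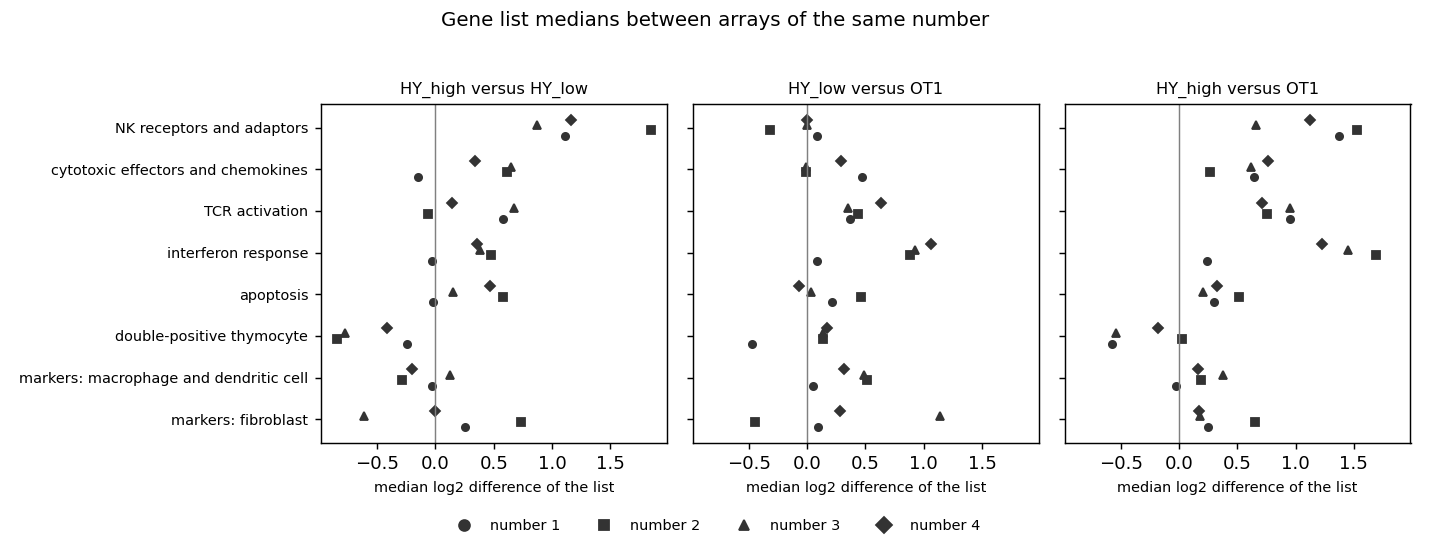
Median log2 difference within each array number, on the axis, for 8 gene lists in the 3 comparisons, where each point stands for 1 number. The NK receptor list lay at 1.11, 1.85, 0.87 and 1.16 in HY_high against HY_low, and the interferon list at 0.24, 1.69, 1.45 and 1.22 in HY_high against OT1.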

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

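The tests of the Cd8b1, interferon and Xist patterns were chosen only after the results were seen, and the counts over other splits of the arrays were planned before.

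An array lying far from the other 3 of its group, relative to the group's range (by Dixon's 95% limit), was found in 17 of 222 groups of values, where chance gives about 1 in 20, or 11.1. Of these 7 fell on arrays numbered 1, 5 on arrays numbered 2, 0 on those numbered 3 and 5 on those numbered 4.

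Cd8b1 on HY_high array 2 had a gap of 0.863 of the range, with an intensity of 1 against 6.18 to 8.26, so that array alone does not make the fall. Xist was low on HY_low array 1 (0.87, 38.1 against 320.5 to 441) and on HY_high array 1 (0.859, 32.7 against 225 to 308). Id2 was high on HY_low array 4 (0.849, 54.5 against 9.03 to 11.9). Thy1 was low on HY_low array 2 (0.87, 301 against 634 to 709), and Emb on OT1 array 4 (0.839, 66.3 against 129 to 147). Plscr1 was at 1 on OT1 array 2 (0.986), where the others had 4.79 to 4.90. Car2 was higher on HY_high array 4 (0.857, 39.98 against 24.8 to 26.5), and Rag1 on the same array (0.934, 5.18 against 1.98 to 2.11). Trav9d-3, on the second of its probe sets, was lower on HY_high array 4 (0.848, 1175 against 1896 to 2066). Ppp1r1a was higher on HY_low array 2 (0.901, 9.32 against 4.99 to 5.31), Lpl on HY_high array 2 (0.833, 12.2 against 1.21 to 1.78) and Apoe on HY_high array 1 (0.869, 3.33 against 1 to 1.17). On OT1 array 1, Klrb1a (0.841), Fcer1g (0.968), Lyz2 (0.965) and Cd83 (0.98) had intensities of 1.65 to 1.93 against at most 1.11, which is close to the lowest value.

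Cd8b1 was lower in HY_high than in HY_low with log2 differences of -4.40, -9.45, -7.40 and -7.38 within the 4 numbers. A lower share of CD8-bearing cells as a whole would lower both chains of CD8 alike, but the change of Cd8b1 minus that of Cd8a was -6.04 on average (SD 1.38). This value cannot decide on a shift from cells with both chains to cells with CD8 alpha alone, which would leave Cd8a. Cd8b1 in HY_high lies near the lowest value, and with the floor at 8 that difference was -5.20 (SD 1.46), from -3.97 to -6.97, as a bound. A mix-up of arrays between the groups cannot be judged by Cd8b1, since 4 of 4 HY_high arrays lay below every other array but the gene was named by a rule that asks for groups without overlap. Cells picked for low CD8 beta before RNA extraction could give the same pattern, and this cannot be told apart. In the labels 0 lines name a sort or gate, but the titles carry unexplained letters, ab in HY_low and aa in HY_high. These letters divide the HY arrays as Cd8b1 does. Neither a loss of Cd8b1 from each cell at the higher dose nor a larger share of cells with only CD8 alpha was tested, and both remain hypotheses.

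The interferon response list was higher in HY_high than in OT1, by 0.24, 1.69, 1.45 and 1.22 within the numbers. RNA from macrophages and dendritic cells would raise their markers with it, but the interferon median exceeded theirs by 0.98 on average (SD 0.51), and Lyz2 (1.16 in OT1, 1.97 in HY_high), Apoe (1.27, 1.40) and Cd74 (6.58, 6.33) stayed low. Ctss (148, 296), Cst3 (15.3, 23.9), C1qb (1.87, 4.05) and H2-Ab1 (1.48, 3.11) were higher in HY_high, and C1qc (2.90, 1.84) and Csf1r (4.72, 3.73) lower. Of the 20 marker genes 0 rose over all genes tested, and 1 did with the block. Ctss passed under 2 of 22 alternatives (lowest limma adjusted p = 0.0142). The marker list, with a median of 0.41, rose less than the interferon list. Most of its genes are dim and the brighter Ctss and Cst3 rose, so these values cannot decide, and such cells stay open. In HY_low Apoe and Lyz2 were at 5.61 and 4.57, and such cells were not tested for the interferon list of HY_low with OT1. RNA from fibroblasts was not tested and stays open too, since their markers had within-number medians of 0.25, 0.65, 0.18 and 0.17 and passed by camera under 7 of 25 alternatives. B cells were not tested either, and their markers had a median of 0.50, with 0.71, 0.65, 0.10 and -0.25 within the numbers. The labels name no sort that would remove such cells, 17 of the 29 interferon genes lay above 8 in OT1, as did 4 of the 20 macrophage and dendritic genes, and 0 of the 29 are in another list. A difference between numbered sets that is alike in all groups cannot give it, since each number holds an array of each group. That follows from the design and not from the values. The lowest within-number median was 0.2415, in number 1, well under the others. These medians cannot decide on a group difference that varies with the number. The peptide, the receptor and the sex or origin of the OT1 cells stay open, untested, although number 4, whose OT1 array has Xist like the HY arrays, had 1.22.

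Xist was low on 3 of the 4 OT1 arrays. On OT1 arrays 2 and 3 Xist was 1 and 1.68 and Eif2s3y 95.5 and 43.0, and on both (2 of 2) Xist lay below and Eif2s3y above every HY array, as male cells on the OT1 arrays numbered 2 and 3 would give. On OT1 array 1 Xist was 9.89 and Eif2s3y 6.12, which HY_high array 1 exceeds at 7.36, so male cells, or a mixture, on that array cannot be told apart from the low Xist of the arrays numbered 1. A difference between numbered sets is argued against for arrays 2 and 3, where Xist in OT1 minus that in HY was -7.92. The comparisons with OT1 may therefore hold a difference of sex or source of the cells.

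In each comparison the 8 arrays were also split in the 35 possible ways into 4 and 4. The real split gave 2, 2 and 15 probe sets past the threshold for HY_high with HY_low, HY_low with OT1 and HY_high with OT1. The highest other split gave 1, 1 and 1, and so 1 of 35 splits gave as many. That share is under 0.05, but splits that ignore the numbers mix in the differences between them, so it does not exclude chance. The numbers pair the arrays, and among the 8 splits that part all 4 pairs the highest other gave 0, 0 and 0, where 8 are too few for a share under 0.05. With the replicate number as a block the real counts were 30, 8 and 118 and the highest others 0, 0 and 1, where 8 splits are too few for a share under 0.05.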

How the results depend on the processing

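The alternatives with a floor at 8, those without the 3 arrays numbered 1, and the double-positive list without Cd8b1 were chosen only after the results were seen.

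Of 112 results for named genes 108 had the same sign under every alternative run. The exceptions, none of them a call, were Trav9d-3 (its brighter probe set in HY cells) and Xist in HY_high with HY_low, and Cd8b1 and Lpl (0 with the floor at 8) in HY_low with OT1. Over 2433 alternative values of named genes 2203 kept their side of the threshold, 95 lost a call and 135 gained one. Over 1698 values of gene lists 1627 kept it, 56 lost a call and 15 gained one. Among uncalled values, 129 changed the direction that camera gave, which need not be the sign of the median. Of the called lists 1 had a median that changed sign, that of apoptosis in HY_high with HY_low without HY_high array 3 (-0.05, not past the threshold). Of 144 alternative counts 99 lay within 1.5 times the reported count and none of the named results reversed.

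HY_high with HY_low had 2 probe sets past the threshold. The number was 1 with scaling to one median (0 higher, 1 lower), 4 with log2 of the value plus 1, 1 with the filter at the median, 7 with array weights and 4 with the floor at 8. Without the filter limma called 0, with 431 of 12422 at an unadjusted p under 0.05. With quantile normalization it was 3 (2 higher, 1 lower). Leaving out single arrays gave 1 to 4. For HY_low with OT1 the number was 2, and 4 with array weights, and quantile normalization or scaling gave 3 (2 higher, 1 lower). For HY_high with OT1 it was 15, and 9 without the filter, 64 with array weights, 8 with the floor at 8 and 9 without the arrays numbered 1. Leaving out single arrays gave 6 to 14.

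With the replicate number as a block the counts were 30, 8 and 118. With the block and the floor at 8 they were 6 and 26 in HY_high with HY_low and HY_high with OT1, and with the block without the arrays numbered 1 they were 30, 11 and 135. Beyond the results given beside their blocked values and the further probe sets in these counts, the block changed no other call.

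Of the gene lists, HY_high with HY_low had 7 past the threshold, and 3 with the filter at the median, 3 with the block and the floor at 8, 1 with an estimated correlation, 1 with fry, and 3 to 6 when single arrays were left out. HY_low with OT1 had 2, and 4 with array weights, 1 with the floor at 8, 1 with the block and that floor, and 0 with an estimated correlation or fry, where 3 lists by each had an unadjusted p under 0.05. HY_high with OT1 had 6, and 4 with an estimated correlation or fry.

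Without the filter limma's prior degrees of freedom were 1.86 against 8.10, and the t statistic of Cd8b1 in HY_high with HY_low was -8.34 against -9.54. Its unadjusted limma p rose from 2.9e-08 to 4.79e-06, and the share of each in this was not separated. Leaving out arrays lowers the number of arrays. The cause of the other differences was not tested. A floor at 8 removes differences among dim probe sets, so signal over background limits what can be said of Klrb1a, Fcer1g, Crtam, St6galnac2 and Trbv13-2, whose calls in HY_high with OT1 ended there, and of Nr4a2, Iigp1, Rag1, Dntt and H2-K1, whose uncalled differences shrank. The call of Capn3 ended too (adjusted p = 0.0671), but its difference stayed at 2.43 against 2.87. Casp1 lies below 8 on all arrays and had no value. Car2 and Cd244a passed with that floor, but with smaller differences, 1.85 and 1.14 in HY_high with OT1 against 3.16 and 2.54.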

Other observations

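The alternatives with a floor at 8 and those without the arrays numbered 1, which enter the ranges below, were chosen only after the results were seen, and Trgv1 and the arrays numbered 1 were singled out after their values were.

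Lists of markers of other cell types did not pass by camera in any comparison as reported. Between HY_high and HY_low their medians were -0.07 for thymic epithelium, 0.05 for fibroblasts, 0.09 for macrophages and dendritic cells (where the mean was -0.01 and the test pointed down), -0.11 for B cells (mean 0.08), 0.29 for NK cells, 0.39 for granulocytes and mast cells, 0.09 for erythroid cells and 0.29 for endothelium. By limma's camera the adjusted p of these 8 lists ran from 0.198 to 0.862. Fibroblast markers had a median of 0.47 between HY_high and OT1 (adjusted p = 0.0552). They passed there under 7 of 25 alternatives (lowest adjusted p = 0.00448, with the mean of a gene's probe sets), and in HY_low against OT1 under 2 of 25, with array weights (0.0403) and with that mean (0.0301). The reported median there was 0.21 (adjusted p = 0.184). The gamma delta T cell and sex-linked lists had 3 and 2 measured genes and were not tested. Car2, which rose in HY_high against OT1, belongs to the erythroid list, whose other 4 genes did not pass.

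Gene lists for general cell functions also did not pass between HY_high and HY_low. Medians were -0.18 for mature conventional T cell genes (limma camera adjusted p = 0.198), 0.01 for T cell receptor signalling components (0.580, with the test pointing down), 0.28 for cytokine receptors (0.198), -0.13 for cell cycle (0.580), 0.02 for immediate early and heat shock genes (0.744), 0.09 for glycolysis (0.336), 0.34 for cholesterol synthesis (0.198) and 0.04 for ribosomal proteins (0.788, with a mean of -0.03).

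In HY_high against OT1, H2-D1, a class I molecule, had a log2 difference of 1.42 on its brightest probe set (adjusted p = 0.490, or 0.00209 with the block), and Trgv1 had 1.46 (adjusted p = 0.199, or 0.000510 with the block). Kit, the stem cell factor receptor, had 3.01 (adjusted p = 0.204, or 0.00731 with the block), and Il6ra had -2.65 (adjusted p = 0.304, or 0.00512 with the block). Tyrobp, an NK receptor adaptor, had 2.25 (adjusted p = 0.406, or 0.0120 with the block). Over the alternatives the adjusted p ranged from 0.00209 to 1 for H2-D1, from 0.000510 to 0.635 for Trgv1 and from 0.000573 to 0.801 for Kit. It ranged from 0.00136 to 1 for Il6ra and from 0.0120 to 1 for Tyrobp. The lowest values of Kit and Il6ra came from the block without the arrays numbered 1.

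The 3 arrays numbered 1 stood apart from the other 9. Their log2 values correlated at 0.735 to 0.850 with arrays of other numbers and at 0.897 to 0.909 among themselves, across probe sets, which are not independent replicates. Arrays of the other numbers correlated at 0.804 to 0.947.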
